A study of Caenorhabditis elegans with 50 samples.

How the data were processed

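Whole-animal polyadenylated RNA of the nematode Caenorhabditis elegans was sequenced as paired ends of 100 cycles in 50 libraries, 5 for each of 10 strains. The labels describe the 5 as separate biological samples of synchronized animals on day 1 of adulthood. Wild type (WT), daf-2(e1370), daf-2(e1368) and the daf-16(mg54) and daf-16(mu86) double mutants of each daf-2 allele make up the daf-2 family of 35 libraries. They grew at 15 °C for the first 72 hours and then at 20 °C. Egg lay of daf-2(e1370) came 6 hours earlier than that of control strains, and no such lead is named for its doubles or WT. glp-1(e2141) and its daf-16(mg54) and daf-16(mu86) doubles make up the glp-1 family of 15 libraries, kept at 25 °C for 48 hours, where these animals lack a germline. No wild type at 25 °C is analysed here, so the glp-1 strains have no mutant against wild type comparison. Groups came from the strain names and replicate numbers 0 to 4 from the labels. The strand setting of the kit is not given in the sources used here, so overlapping and antisense genes cannot be told apart.

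The values are estimated counts that the authors deposited for each gene entry and library, in 1 table with 0 columns of other samples. The submitters' processing notes name FastQC 0.10.1, cutadapt, TopHat2 2.0.9, Bowtie2 2.1.0, Cufflinks, Cuffdiff 2.1.1 and the genome build ce10, while the role of each tool, the filters and the annotation are not given in the sources used here. Of the values above 0, 72.2% lay within 0.02 of a whole number, and all were rounded before testing. The table holds 34207 entries. The 314 that name no gene held 0.187% to 0.48% of a library's fragments and stayed out of library sizes and tests. Of the others, entries with the same name and locus were summed (849 entries at 414 name and locus pairs), which left 33458. The 4488 entries that name several genes held 25.4% to 35.2% and were tested as entries, never credited to a single gene. Coordinates are those of the deposited table on ce10, where neighbouring entries can carry the span of the whole bundle of overlapping models. Another build, WBcel235, served for gene names and biotypes alone.

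An exact 0 in this table can be a failed estimate. The vitellogenins vit-2, vit-4, vit-5 and vit-6, the ribosomal protein genes rpl-4, rps-9 and rpl-41, the ubiquitin entry ZK1010.2,ubq-2 and the ribosomal RNA entry rrn-1.1 were at 0 in all 50 libraries, vit-1 was at 0 in 45 and the elongation factor gene eef-1A.1 in 35. In all, 3 large loci with 417 entries were at 0 in every library. A locus was therefore treated as not estimated in a family when every library of a strain was at 0 over the whole locus while another strain of that family averaged at least 1000 fragments there. This left out 10 loci (946 entries) in the daf-2 family and 1 locus (165 entries) in the glp-1 family. The minimum was picked after the loci caught by 3 values had been seen: 100 left out 12 loci and 10000 left out 9 in the daf-2 family, and each left out 1 in the glp-1 family. A gene at 0 is called listed at 0, with no fold.

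Library totals, in units of 1e6 fragments, ran from 19.89 to 34.25 in the daf-2 family apart from daf-2(e1370) replicate 2, which had 2.37, and from 13.82 to 23.81 in the glp-1 family. Replicates were compared in all 100 pairs within strains over entries with at least 20 fragments, and chi-square per degree of freedom was 7.21 to 177, so no pair looked like a library deposited again.

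Comparisons were fixed before the data were examined, together with the tests, the gene lists, the rule for named genes and the other settings to be tried. They are each single mutant minus each of its daf-16 doubles, each daf-2 allele minus WT, the mean of the doubles minus WT, mg54 minus mu86 doubles, and the difference of the daf-16 effect (single mutant minus the mean of its doubles on the log2 scale) between backgrounds. Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr, robust quasi-likelihood fits on strain alone, and Benjamini-Hochberg adjusted p under 0.05. Each family was fitted alone, and the difference between daf-2(e1370) and glp-1 was fitted on all 50 libraries. Every adjusted p of a gene is from this test unless another tool is named. Errors beside log2 differences are standard errors (SE) from the quasi-likelihood F, errors beside CPM (counts scaled to library size) are standard deviations (SD), and n is 5 libraries per strain. CPM values use TMM-scaled library sizes.

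Gene lists numbered 30, drawn from textbook knowledge and gene class names, with 1338 members. Of these, 1027 have an entry that names them alone, and 118 lie in 52 entries that name only members of the same list, each used as 1 entry. Another 183 occur only in entries shared with other genes and were not used, and 10 were not found. These numbers count a gene once for each list. The lists cover class I and class II DAF-16 genes, small heat shock proteins, large chaperones, antioxidant and metal defence, glutathione S-transferases, cytochrome P450 enzymes, UDP-glucuronosyltransferases, vitellogenins, lysozymes with saposin-like and antimicrobial peptides, C-type lectins, fatty acid metabolism, glyoxylate and sugar metabolism, osmolyte and desiccation tolerance, autophagy, proteasome, cytosolic ribosomal proteins, respiratory chain, insulin-like peptides, insulin/IGF-1 pathway components, longevity transcription regulators, collagens, and markers of the oogenic germline, sperm, embryo, intestine, body wall muscle, pharynx, neurons and hypodermis with molting. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, again with a correlation estimated per list, and with fry. The 145 tests (29 lists in 5 comparisons) were adjusted together. Counts of members are given over all genes tested and adjusted over the list alone.

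Named genes followed a fixed rule. It takes daf-16, daf-2 and glp-1 always. In each background it takes genes called with both daf-16 alleles in the same direction with a mean of at least 5 CPM, ranked by the smaller change, up to 10 higher and 8 lower with a gene class name and up to 2 each with a sequence name. It takes genes called in all 6 single against double comparisons, up to 12 higher and 8 lower, and genes called in both daf-2 alleles against WT, up to 8 in each direction. It takes up to 5 in each direction between daf-16 alleles, up to 6 for each sign of the differences between backgrounds, and up to 4 members of a described list by smallest adjusted p. Genes outside the rule are said to be chosen after their values were seen.

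The other settings were RLE factors, no filter, a filter of 5 CPM in 5 libraries, DESeq2 1.42.0, an absolute log2 change of at least 1, the replicate number as a block, fits of the groups compared alone, all 50 libraries in 1 fit, and leaving out each library in turn. Added after seeing the data were the treatment of loci at 0, unsummed entries, a block within the compared pair of strains, and fits without replicates 0 and 1 of both daf-2(e1370) doubles. Same-numbered libraries deviated together in every pair for daf-2(e1368) against its mg54 double (correlations 0.13 to 0.8) and for the mg54 against mu86 doubles of daf-2(e1370) (0.73 to 0.89), so blocked values stand beside these results. In the other comparisons at least 1 pair was at 0.07 or lower. Still, 4 of 5 pairs were over 0.1 for daf-2(e1370) against its mg54 double, daf-2(e1368) against its mu86 double, and the doubles of daf-2(e1368). For daf-2(e1368) against mu86 the same number was the best match for 8 of 10 libraries. Replicates thus shared deviations in more of the daf-2 family, where library numbers run replicate by replicate over all strains. Replicate can be a block there, which the main fits on strain alone do not take out.

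The edgeR step was tested on simulated counts with known fold changes. For daf-2(e1370) against its mg54 double (11654 entries) it recovered 49.3% of 1.5-fold, 83.6% of 2-fold and 95.5% of 4-fold changes, with 5.6% of calls wrong. The same shares were 61.2%, 83.6% and 97%, with 3.6% wrong, for daf-2(e1368) against its mg54 double (11664 entries), and 26.9%, 74.6% and 95.5%, with 0.8% wrong, for glp-1 against its mg54 double (10296 entries). DESeq2 gave 11.7%, 10.6% and 18.2% wrong calls on these. With the proteasome list shifted in the simulated daf-2(e1370) libraries its adjusted p was 2.6e-138, and with no list shifted camera made 0 calls in 145 tests. Genes were drawn independently, so this test could not show false calls that arise from correlated list members. For comparisons that share control libraries, unchanged groups were simulated 20 times at the mean level of the controls. The controls were simulated too, and genes were drawn independently. The simulations thus lack the structure of the real libraries, and a simulated overlap of 0 does not measure what real shared libraries add. The real controls were also split into parts of 2 and 3 libraries.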

Results

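Messenger RNA of whole Caenorhabditis elegans adults was counted in 10 strains, with 5 libraries each, to ask which genes depend on daf-16 in long-lived animals. DAF-16 is the FOXO transcription factor that acts when insulin/IGF-1 signalling is low. daf-2 encodes the insulin/IGF-1 receptor, and 2 of its reduction-of-function alleles were used, e1370 and e1368. glp-1 encodes a Notch receptor needed by germline stem cells, and animals with the e2141 allele have no germline at the temperature used. Each of these long-lived single mutants was compared with double mutants that also carry daf-16(mg54), a nonsense allele, or daf-16(mu86), a deletion. daf-2(e1370) replicate 2 was shallow, with 2.37 in units of 1e6 fragments. Differences are log2 values, single mutant minus double mutant unless stated otherwise, with SE.

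The mutated gene itself was examined first. The daf-16 transcript (chromosome I, 10750402 to 10776748 on ce10) stood at 216 ± 5.64 CPM in WT (SD, n = 5), 208 ± 35.6 in daf-2(e1370) and 201 ± 7.96 in daf-2(e1368). It was lower in the mg54 doubles of daf-2, at 105 ± 6.37 CPM with e1370 and 103 ± 6.44 with e1368, differences of 0.98 ± 0.09 (adjusted p = 8.46e-10) and 0.96 ± 0.09 (adjusted p = 7.19e-09). In the mu86 doubles it stood at 184 ± 25.6 and 194 ± 24.1 CPM, with differences that did not pass (adjusted p = 0.207 and 0.872), so the total over this gene does not check the mu86 label there. In the glp-1 family it was 203 ± 41.4 CPM in the single mutant, 160 ± 46.8 with mg54 (0.34 ± 0.18, adjusted p = 0.416) and 433 ± 47.4 with mu86 (−1.09 ± 0.18, adjusted p = 0.00399). An entry at the same locus, H36N01.2,H36N01.3,R13H8.4, chosen after its values were seen, separated every mu86 library from every other one. It held 1998 to 4521 fragments in the mu86 doubles of daf-2(e1368), 2340 to 5016 in those of daf-2(e1370) and 3626 to 6290 in those of glp-1, against 2 to 41 in the libraries of the other 7 strains. The mg54 minus mu86 differences were −8.87 ± 0.82, −8.01 ± 0.78 and −8.71 ± 0.20 in daf-2(e1370), daf-2(e1368) and glp-1 (adjusted p = 1.65e-08, 5.7e-08 and 3.41e-13).

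daf-2 mRNA (chromosome III, 2995416 to 3028848) was 243 ± 112 CPM in daf-2(e1370) and 131 ± 9.51 in WT (0.87 ± 0.17, adjusted p = 0.00019), and higher than in both e1370 doubles (0.77 ± 0.16 and 0.83 ± 0.17). Its shallow replicate 2 alone read 442 CPM. The glp-1 mRNA (chromosome III, 9092172 to 9101181) was 237 ± 15.7 CPM in WT and 17.3 ± 2.35, 16.8 ± 1.36 and 14.1 ± 1.58 in the glp-1 strains. The WT animals grew at another temperature than the glp-1 strains, so this difference was not tested.

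**Figure D1:**
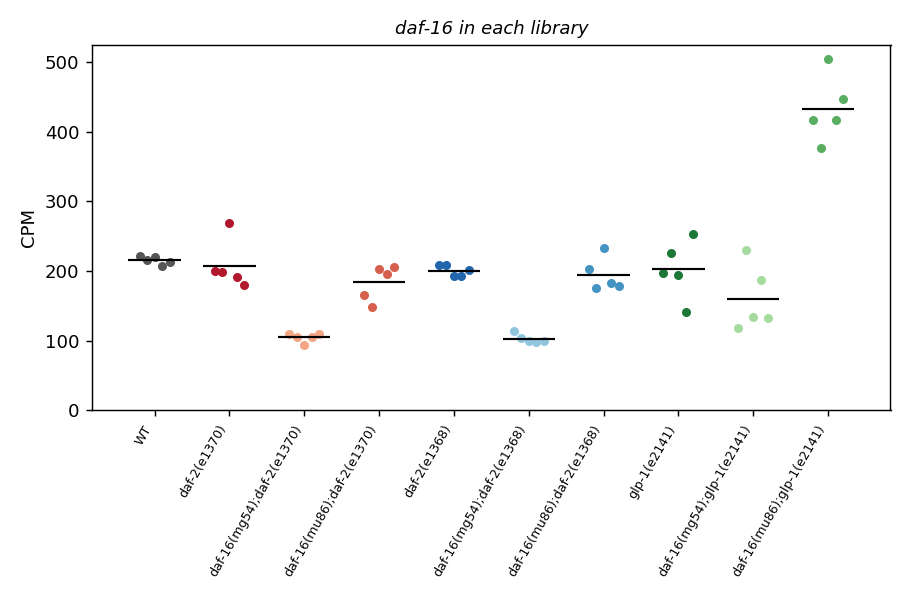
CPM of daf-16 in each of the 50 libraries by strain, with a line at the mean of 5. The mg54 doubles of daf-2 average 105 and 103 CPM, below WT at 216, while the mu86 double of glp-1 averages 433.

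The first comparison asked what daf-16 contributes in daf-2(e1370), the stronger of the 2 alleles. Its egg lay came 6 hours earlier than that of control strains, a lead that goes along with genotype in every daf-2(e1370) comparison. The metallothionein gene mtl-1 (chromosome V, 6691281 to 6691943) stood at 63 ± 23.4 CPM in daf-2(e1370) and at 0.699 ± 0.395 and 0.649 ± 0.341 in the doubles. The differences were 6.49 ± 0.48 with mg54 and 6.6 ± 0.48 with mu86 (adjusted p = 4.11e-12 and 2.83e-12). The lysosomal lipase gene lipl-1 (chromosome V, 12919990 to 12921674, at 5.74 ± 0.32 and 4.65 ± 0.3) rose, as did lipl-2 (chromosome V, 9791563 to 9793197, at 5.47 ± 0.5 and 5.35 ± 0.49). So did the ferritin gene ftn-1 (chromosome V, 7546525 to 7547544, at 5.06 ± 0.43 and 4.45 ± 0.42) and sdz-24 (7.54 ± 0.43 and 7.47 ± 0.43). H39E23.3 (chromosome V, 14107795 to 14110036) was at 199 ± 22 CPM, against 0.0891 ± 0.0543 and 0.0292 ± 0.0322 in the doubles, where single libraries held 0 to 4 fragments. T12D8.5 averaged 20.8 ± 10.8 CPM and was listed at 0 in all libraries of both doubles and of WT.

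Lower in daf-2(e1370) than in both doubles were oac-20 (chromosome V, 15978704 to 15981646, at −4.25 ± 0.17 and −4.21 ± 0.17, adjusted p = 6.87e-19 and 7.3e-19) and dod-24, whose name stands for downstream of daf-16 (chromosome IV, 12940150 to 12941328, at −3.85 ± 0.36 and −4.87 ± 0.37). Also lower were the cytochrome P450 gene cyp-13A2 (−3.25 ± 0.29 and −3.17 ± 0.29), the glycerol-3-phosphate dehydrogenase gene gpdh-1 (−3.16 ± 0.55 and −3.31 ± 0.55) and the methionine sulfoxide reductase gene msra-1 (−2.37 ± 0.23 and −2.36 ± 0.23). Lower in the same way were ugt-53 (−2.72 and −2.75), dod-23 (−2.57 and −2.7), dod-17 (−2.56 and −2.92), CELE_F55G11.2 at the same locus as dod-17 (−5.11 and −5.79), and C41A3.6 (−4.04 and −4.16). The small nuclear RNA gene sup-6, the RNase MRP RNA gene mrpr-1 and the histone genes his-59, his-62 and his-64, near-identical copies of which exist elsewhere, also ranked among the higher genes, at 4.45 to 7.62. They rest on replicate 2. Without it the mg54 differences were 1.43, −0.24, 0.12, −0.34 and 0.06 (adjusted p = 0.123, 0.64, 0.664, 0.258 and 0.894). The mu86 differences were 1.47, 0.46, 0.11, −0.4 and 0.33 (adjusted p = 0.118, 0.414, 0.733, 0.199 and 0.491).

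In all, 2621 entries passed with mg54 (1395 higher and 1226 lower in daf-2(e1370), of 11774 tested) and 2536 with mu86 (1319 and 1217). Of these, 1097 were higher and 933 lower with both alleles. Independent lists of these sizes would share 156.3 and 126.7. Unchanged groups, simulated together with the single mutant libraries they share, had 0 in common. With those libraries split into parts of 2 and 3 the overlap was 668 and 323 (85.9 and 46.7 for independent lists). When the compared strains were fitted alone, 1014 and 1313 entries passed, and with the replicate number as a block 5347 (3059 and 2288) and 4107 (2179 and 1928). The majority turned with all 50 libraries in 1 fit, to 1258 higher and 1530 lower with mg54 and 1129 and 1352 with mu86. With mu86 it also turned, to 1306 and 1391, without replicates 0 and 1 of both daf-2(e1370) doubles, a setting chosen after seeing the data. Without the shallow replicate 2 the counts were 2350 and 2465, of which 2058 and 2138 were among the calls with it.

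**Figure D2:**
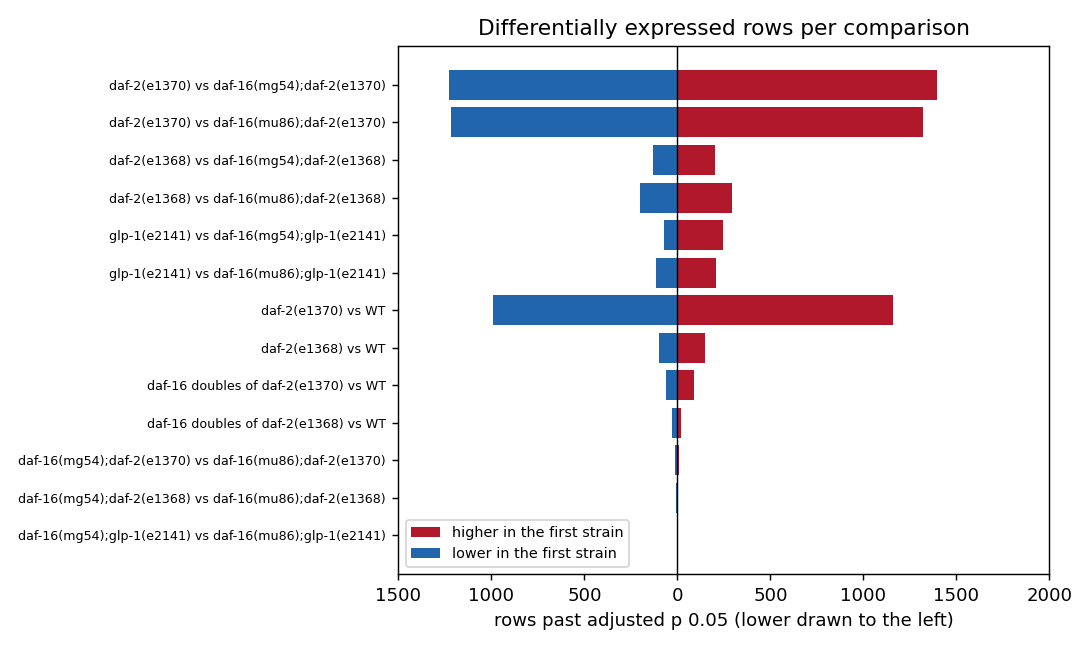
Number of entries past an adjusted p of 0.05 in each of 13 comparisons, bars to either side for higher and lower in the first named group. daf-2(e1370) against its doubles gives 2621 and 2536, and the other single mutants against their doubles give 316 to 499.

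Gene groups in daf-2(e1370) were tested as single mutant minus the mean of both doubles. Over all comparisons camera passed 58 lists with its preset correlation and 10 with an estimated one, and among 100 assignments of the libraries, the real one included, the highest other passed 57. All 17 tested class I genes, textbook targets raised in daf-2 mutants, rose (17 adjusted over the list alone; median 2.12, camera adjusted p = 1.06e-24, and adjusted p = 5.18e-05 with an estimated correlation). Among them were lea-1, a late embryogenesis abundant protein gene (3.22 ± 0.08), sod-3, the mitochondrial manganese superoxide dismutase (4.75 ± 0.23), and aakg-4, an AMP-activated kinase subunit (1.87 ± 0.1). Of 5 class II genes, textbook genes lowered in daf-2 mutants, 3 fell (3 adjusted over the list alone; median −2.63, adjusted p = 0.000206, and adjusted p = 0.00423 with an estimated correlation), while ins-7 was at −0.22 ± 0.31. These calls held with an estimated correlation, and the following ones were lost with it. Lysozymes, saposin-like and antimicrobial peptides rose in 13 of 27 and fell in 0 (14 and 0 adjusted over the list alone; adjusted p = 3.89e-06, and adjusted p = 0.403 with an estimated correlation), led by spp-2 (3.92 ± 0.15) and lys-7 (3.72 ± 0.24). Glutathione S-transferases, which conjugate toxins, rose in 16 and fell in 3 of 34 (18 and 3 adjusted over the list alone; adjusted p = 0.000379, and adjusted p = 0.462 with an estimated correlation), with gst-29 at 5.03 ± 0.3. Of 18 insulin-like peptide genes 10 rose and 2 fell (10 and 2 adjusted over the list alone; adjusted p = 0.00652, and adjusted p = 0.473 with an estimated correlation), such as ins-10 (3.65 ± 0.43) and ins-35 (4.09 ± 0.48).

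Lower as lists in daf-2(e1370) were genes of protein synthesis, folding and turnover. Cytosolic ribosomal protein genes fell in 34 of 53 and rose in 0 (39 lower adjusted over the list alone; median −0.35, adjusted p = 1.46e-10, and adjusted p = 0.522 with an estimated correlation), with rps-23 at −0.45 ± 0.09. Proteasome subunits fell in 14 of 19 and rose in 0 (16 lower adjusted over the list alone; median −0.33, adjusted p = 2.1e-06, and adjusted p = 0.49 with an estimated correlation), with pbs-7 at −0.5 ± 0.1. Large chaperones fell in 8 and rose in 1 of 15 (9 and 1 adjusted over the list alone; adjusted p = 0.00861, and adjusted p = 0.557 with an estimated correlation), with the cytosolic chaperonin gene cct-4 at −0.4 ± 0.09 while hsp-70 stood at 1.81 ± 0.4. Of 6 insulin/IGF-1 pathway genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.0134, adjusted p = 0.266 with an estimated correlation, and 0.0521 without daf-2(e1370) replicate 2), led by the kinase gene pdk-1 (1.2 ± 0.11).

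Sperm markers passed as a list in daf-2(e1370) (2 of 51 rose, 0 fell, 0 adjusted over the list alone, adjusted p = 0.0115, and adjusted p = 0.825 with an estimated correlation). Neuron markers passed too (4 of 25 rose, 0 fell, 3 adjusted over the list alone, adjusted p = 0.0144, and adjusted p = 0.754 with an estimated correlation). The sperm call ended without replicate 1 of the mg54 double (0.0951) or of the mu86 double (0.0515). The doubles are not uniform here. The 24 major sperm protein genes averaged 8.3 and 2.3 CPM in replicates 0 and 1 of the mg54 double against 54.1 to 61.2 in its other libraries. In the mu86 double they averaged 18.6 and 11.8 against 73.6 to 79.4. In those 4 libraries the median member of the sperm, pharynx, body wall muscle, collagen and neuron lists differed by −2.85, −1.74, −1.19, −0.96 and −0.92. Proteasome genes and large chaperones were higher there (medians 0.27 and 0.28), close in size to their drop in daf-2(e1370) (medians −0.33 and −0.24). Without these libraries the neuron and large chaperone calls ended (adjusted p = 0.608 and 0.203), while the proteasome list still passed (0.00154). With them left out, sperm and body wall muscle markers turned to lower against the doubles (0.0371 and 0.0491), and pharynx, antioxidant and respiratory chain lists passed there (0.00452, 0.0278 and 0.0116). Against WT, where these libraries are not compared, large chaperones were lower in daf-2(e1370) too (1 of 15 rose and 6 fell, 1 and 8 adjusted over the list alone; median −0.22, adjusted p = 0.011, and adjusted p = 0.574 with an estimated correlation).

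The other lists did not pass in daf-2(e1370), with camera adjusted p and members higher and lower over all genes tested. Stress lists were small heat shock proteins (3 and 0 of 8, 3 and 1 adjusted over the list alone, adjusted p = 0.212), antioxidant and metal defence (5 and 2 of 17, 6 and 2 adjusted over the list alone, 0.17) and cytochrome P450 enzymes (11 and 4 of 37, 0.234). Next came UDP-glucuronosyltransferases (8 and 12 of 39, 0.696), C-type lectins (21 and 23 of 80, 23 and 26 adjusted over the list alone, 0.655) and osmolyte tolerance (2 and 2 of 7, 0.209). Antioxidant genes passed at 0.0251 without replicate 2. Metabolic lists were fatty acid metabolism (8 and 6 of 28, 9 and 6 adjusted over the list alone, 0.392), with fat-7, a stearoyl-CoA desaturase (chromosome V, 7151427 to 7153112), at −1.99 ± 0.18. Next came glyoxylate and sugar metabolism (8 and 4 of 20, 9 and 4 adjusted over the list alone, 0.0792, and 0.0379 without replicate 0), with the glyoxylate cycle gene icl-1 at 2.89 ± 0.19. The respiratory chain list (1 and 6 of 17, 1 and 7 adjusted over the list alone, 0.145, and 0.0486 without replicate 4) missed as well. Autophagy genes (3 and 1 of 14, 3 and 2 adjusted over the list alone, 0.914) and longevity regulators (5 and 1 of 22, 0.243) likewise missed. So did oogenic germline (0 and 4 of 26, 0 adjusted over the list alone, 0.06), embryo (2 and 2 of 12, 0.937) and intestine (2 and 4 of 11, 0.776) markers. Body wall muscle (1 and 1 of 18, 0.721), pharynx (0 and 2 of 9, 0.208) and hypodermis markers (6 and 1 of 23, 0.212) and collagens (18 and 5 of 88, 0.0685) missed too. Collagens passed (0.00789 to 0.0389) without any 1 of daf-2(e1370) replicates 0 and 1 and replicates 2, 3 and 4 of either double. Oogenic markers passed (0.013 to 0.0393) without any 1 of daf-2(e1370) replicates 2 and 4 and replicates 2 and 3 of either double. In the autophagy list the median (0.08) and mean (−0.01) differed in sign, and in the embryo list the median (−0.03) and mean (0.35). The UDP-glucuronosyltransferase list had a median of 0.03 and a mean of 0.02, while its test pointed down. No vitellogenin could be tested, since 4 of the 5 found were listed at 0 in every library and the remaining one in 45.

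The same question was asked in daf-2(e1368), the weaker allele. The gene lea-1 held 1730 ± 252 CPM in daf-2(e1368) against 244 ± 28 in the mg54 double and a mean of 259 in the mu86 double (2.82 ± 0.1 with mg54 and 2.74 ± 0.1 with mu86, adjusted p = 1.79e-19 and 2.09e-19). Also higher were nspa-4 (3.23 ± 0.54 and 3.34 ± 0.55), the saposin-like gene spp-2 (2.34 ± 0.18 and 2.51 ± 0.19), the lysozyme gene lys-7 (2.39 ± 0.3 and 1.8 ± 0.29) and bcmo-2 (1.87 ± 0.14 and 1.88 ± 0.14). Others that rose were the small heat shock protein gene sip-1 (1.52 ± 0.17 and 1.46 ± 0.17), icl-1 (1.28 ± 0.23 and 1.58 ± 0.24), the catalase gene ctl-3 (1.16 ± 0.26 and 1.16 ± 0.26), the globin gene glb-1, clec-52, Y54G2A.36 and ZC395.5. Lower were dod-24 (−2.63 ± 0.31 and −2.97 ± 0.31), CELE_C32H11.4 (−2.53 ± 0.3 and −2.49 ± 0.3), CELE_Y39B6A.24 (−2.08 ± 0.35 and −2.53 ± 0.36), ugt-53, cutl-18, oac-20, dod-23, clec-10 and fat-7 (−1.23 ± 0.19 and −1.02 ± 0.19). The gene tag-38 was also called (−1.2 ± 0.33, adjusted p = 0.0405, and −1.33 ± 0.33). Its mg54 call ended (0.0668 to 0.208) without any 1 of daf-2(e1368) replicates 0, 1, 3 and 4 or mg54 double replicates 0 and 2.

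With mg54, 333 entries passed (200 higher and 133 lower), and with mu86, 499 (296 and 203). With the replicate number as a block, 696 passed with mg54, and 1544 (747 higher and 797 lower) when only this pair of strains was fitted with the block, and 1035 passed with mu86. When loci at 0 in a strain were kept, a setting chosen after seeing the data, the majority turned, to 220 higher and 240 lower with mg54 and 323 and 399 with mu86. Both alleles shared 161 higher and 94 lower, against 5 and 2.3 for independent lists, 0 in the simulation, and 69 and 35 with split single mutant libraries (1.4 and 0.5 for independent lists).

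Of the groups in daf-2(e1368), class I genes rose in 14 of 17 (14 adjusted over the list alone; median 1.01, adjusted p = 2.21e-33, and adjusted p = 1.26e-05 with an estimated correlation). Class II genes fell in 2 of 5 (3 adjusted over the list alone; adjusted p = 3.04e-06, and adjusted p = 0.000444 with an estimated correlation). Calls that were lost with an estimated correlation include lysozymes and related peptides (8 rose and 1 fell of 27, 9 and 1 adjusted over the list alone; adjusted p = 2.1e-06, and adjusted p = 0.388 with an estimated correlation). They also include antioxidant and metal defence (5 and 1 of 17, 6 and 1 adjusted over the list alone; adjusted p = 1.07e-05, and adjusted p = 0.187 with an estimated correlation), and insulin/IGF-1 pathway genes (3 and 0 of 6, 4 and 0 adjusted over the list alone; adjusted p = 0.000149, and adjusted p = 0.054 with an estimated correlation). UDP-glucuronosyltransferases, which attach sugar to toxins, fell in 5 and rose in 1 of 39 (10 and 1 adjusted over the list alone; adjusted p = 0.000282, and adjusted p = 0.49 with an estimated correlation), with ugt-53 at −1.63 ± 0.23 and ugt-18 at 2.63 ± 0.42. Osmolyte and desiccation genes passed as higher (2 and 1 of 7, 2 and 1 adjusted over the list alone; median 0, adjusted p = 0.0188, and adjusted p = 0.115 with an estimated correlation), but not without daf-2(e1368) replicate 2 (0.0619) or with the replicate block (0.103). Glutathione S-transferases passed too (3 and 1 of 34, 4 and 1 adjusted over the list alone; adjusted p = 0.0247, and adjusted p = 0.611 with an estimated correlation), but not without daf-2(e1368) replicate 0 (0.0567). The glyoxylate and sugar metabolism call (3 and 1 of 20, 7 and 2 adjusted over the list alone; adjusted p = 0.0325, and adjusted p = 0.522 with an estimated correlation) ended without daf-2(e1368) replicate 1, 2 or 3, mg54 double replicate 0, 1 or 4 or mu86 double replicate 0 or 1 (0.0504 to 0.184). Ribosomal protein genes passed as lower (median −0.09, adjusted p = 0.00467, and adjusted p = 0.793 with an estimated correlation), but edgeR called 0 of 53, with 0 at an unadjusted p under 0.05, and DESeq2 called 0. That call ended without daf-2(e1368) replicate 0 or 4 (0.187 and 0.353). Pharynx markers (median −0.74, adjusted p = 0.0035, and adjusted p = 0.473 with an estimated correlation) and sperm markers (median −0.45, adjusted p = 0.00132, and adjusted p = 0.793 with an estimated correlation) passed as lower lists, although edgeR called 0 members of either (4 of 9 and 0 of 51 at an unadjusted p under 0.05) and DESeq2 also called 0.

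The third background was glp-1(e2141), where longevity follows loss of the germline. There mtl-1 stood at 145 ± 90.6 CPM against 10.4 ± 4.49 with mg54 and 7.69 ± 5.97 with mu86 (3.8 ± 0.49 and 4.23 ± 0.5, adjusted p = 0.000629 and 0.000234). The gene sod-3 (chromosome X, 17087807 to 17094023) stood at 27.1 ± 7.29 CPM against 4.47 ± 0.418 and 5.13 ± 1.35 (2.6 ± 0.2 and 2.39 ± 0.2, adjusted p = 4.53e-06 and 7.99e-06). Also higher were glb-1 (3.46 ± 0.5 and 3.31 ± 0.49), gst-29 (2.83 ± 0.45 and 2.72 ± 0.45), lys-7 (2.24 ± 0.33 and 1.82 ± 0.33) and spp-2 (2 ± 0.34 and 1.7 ± 0.34). Others were F21C10.11 (3.56 ± 0.49 and 2.99 ± 0.47), the sulfide quinone oxidoreductase gene sqrd-1 (1.68 ± 0.3 and 1.34 ± 0.29) and dod-3 (1.77 ± 0.38 and 1.5 ± 0.38). The entry CELE_F56D6.9 averaged 15.9 ± 20.8 CPM against 0.0904 ± 0.149 and 0.0195 ± 0.0269. In this entry replicate 0 of glp-1 held 52.6 CPM, and without it the mean was 6.79 and the differences went from 7.46 and 9.11 to 6.24 and 7.89 (adjusted p = 0.000643 and 0.000304). The mu86 difference of glb-1 was 2.72 without that library, and that of mtl-1 was 4.83 without replicate 3 of the mu86 double, whose mean was then 5.07 CPM. Lower in glp-1 were pme-4, a poly(ADP-ribose) glycohydrolase gene (−2.1 ± 0.22 and −2.73 ± 0.22, adjusted p = 7.75e-05 and 6.4e-06), and the infection response gene irg-1 (−1.87 ± 0.44 and −2.75 ± 0.45). Also lower were CELE_F35E12.5 (−1.76 ± 0.31 and −1.59 ± 0.3), M60.2 (−1.34 ± 0.25 and −1.23 ± 0.25), cyp-14A5 (−1.02 ± 0.13 and −1.4 ± 0.13), the P-glycoprotein gene pgp-8 (−0.9 ± 0.14 and −1.31 ± 0.14), srh-70, gst-38, dmsr-2 and aat-6.

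The glp-1 family has a structure beyond strain. On the first principal component (31.2% of variance) glp-1 replicate 0 (−58.9), mg54 replicate 2 (−32.9) and mu86 replicate 3 (−41.5) stood apart from the other libraries of their strains. They also held the highest mtl-1 values of their strains, at 305, 17.6 and 18.2 CPM, and the cause was not tested. Several of these glp-1 calls lay near the threshold, and leaving out any 1 of several libraries ended them while the direction held. The mg54 call of dod-3 ended without glp-1 replicate 0 or 2 or mg54 double replicate 0 or 1 (adjusted p = 0.0515 to 0.0643). The gst-38 call ended without glp-1 replicate 1, 2 or 4 or mg54 replicate 3 (0.0515 to 0.0634), and that of dmsr-2 without mg54 replicate 3 (0.0509). The irg-1 call ended without any 1 library but glp-1 replicate 1 and mg54 replicate 2 (0.052 to 0.0866), and that of srh-70 without any but glp-1 replicate 3 and mg54 replicate 1 (0.0714 to 0.123). The aat-6 call ended without glp-1 replicate 0, 2 or 4 or mg54 replicate 0, 1, 3 or 4 (0.0559 to 0.0934). With mu86, dod-3 was lost without glp-1 replicate 0, 2 or 4 or mu86 replicate 0, 1, 2 or 4 (0.0688 to 0.121). There sqrd-1 was lost without mu86 replicate 0, 1, 2 or 4 (0.053 to 0.0621) and dmsr-2 without glp-1 replicate 0, 2 or 4 or mu86 replicate 2 or 4 (0.0707 to 0.085). Likewise aat-6 was lost without glp-1 replicate 0, 2 or 4 or mu86 replicate 0, 1, 2 or 4 (0.0544 to 0.11).

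With mg54, 316 of 10391 entries passed (245 higher and 71 lower), and with mu86, 322 (205 and 117). The mg54 count was 181, 191 and 199 without glp-1 replicates 0, 2 and 4 and 162, 208 and 174 without mg54 replicates 0, 1 and 3. The mu86 count was 200 without glp-1 replicate 0 and 196, 204, 586 and 190 without mu86 replicates 1, 2, 3 and 4. With the replicate number as a block 147 and 147 passed, and DESeq2 called 623 and 603. With all 50 libraries in 1 fit the split was 304 higher and 420 lower with mg54 and 248 and 279 with mu86, and 192 passed with mu86 when the pair was fitted alone. Both alleles shared 158 higher and 43 lower, against 4.8 and 0.8 for independent lists, 0 in the simulation, and 63 and 7 with split libraries (1.2 and 0.1 for independent lists).

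Class I genes rose in 11 of 16 in glp-1 (13 adjusted over the list alone; median 0.81, adjusted p = 2.08e-18, and adjusted p = 0.00573 with an estimated correlation), although lea-1 was at 0.16 ± 0.12. Each further call was lost with an estimated correlation. Class II genes fell in 1 of 6 (4 adjusted over the list alone; adjusted p = 0.00102, and adjusted p = 0.266 with an estimated correlation). Ribosomal protein genes fell in 21 of 58 and rose in 0 (41 lower adjusted over the list alone; median −0.26, adjusted p = 1.79e-23, and adjusted p = 0.183 with an estimated correlation), with rpl-11.1 at −0.72 ± 0.12. Glyoxylate and sugar metabolism genes rose in 8 and fell in 0 of 20 (12 and 1 adjusted over the list alone; adjusted p = 1.8e-06, and adjusted p = 0.183 with an estimated correlation). They include the phosphoenolpyruvate carboxykinase gene pck-1 (1.42 ± 0.28) and the glycolytic genes enol-1 (0.41 ± 0.07) and pyk-2 (0.38 ± 0.07). Fatty acid genes rose in 5 and fell in 1 of 29 (9 and 1 adjusted over the list alone; adjusted p = 0.00236, and adjusted p = 0.198 with an estimated correlation), with the lipase gene lipl-4 at 1.99 ± 0.28. Hypodermis and molting markers fell in 4 of 23 and rose in 0 (11 lower adjusted over the list alone; adjusted p = 7.16e-06, and adjusted p = 0.198 with an estimated correlation), with qua-1 at −0.8 ± 0.15. Higher as well were lysozymes and related peptides (5 and 0 of 26, 6 adjusted over the list alone; adjusted p = 3.04e-06, and adjusted p = 0.28 with an estimated correlation) and antioxidant defence (4 and 0 of 17, 5 adjusted over the list alone; adjusted p = 0.000395, and adjusted p = 0.156 with an estimated correlation). So were glutathione S-transferases (4 and 1 of 34, 5 and 1 adjusted over the list alone; adjusted p = 0.00125, and adjusted p = 0.346 with an estimated correlation) and cytochrome P450 enzymes (5 and 2 of 35, 11 and 2 adjusted over the list alone; adjusted p = 0.00164, and adjusted p = 0.187 with an estimated correlation). The last were small heat shock proteins (2 and 0 of 7, 4 adjusted over the list alone; adjusted p = 0.0131, and adjusted p = 0.348 with an estimated correlation).

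A core of genes changed in the same direction in all 6 single against double comparisons. Genes mtl-1, gst-29, sod-3, bcmo-2, lys-7, spp-2, sdz-24, glb-1, the gut esterase gene ges-1, the amino acid transporter gene aat-1, the transthyretin-related gene ttr-5 and aakg-4 were the leading 12 with class names, all higher. The smallest of the 6 differences was 3.46 ± 0.44 for mtl-1, 2.72 ± 0.45 for gst-29 and 2.39 ± 0.2 for sod-3. It was 1.81 ± 0.23 for bcmo-2, 1.8 ± 0.29 for lys-7, 1.7 ± 0.34 for spp-2, 0.98 ± 0.07 for ges-1 and 0.54 ± 0.12 for aakg-4. No gene with a class name and at least 5 CPM was lower in all 6. In total 69 of 9824 entries tested in all 6 passed (60 higher and 9 lower, 45 and 8 of them naming 1 gene). In 20 simulations of unchanged groups the highest number was 0.

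**Figure D3:**
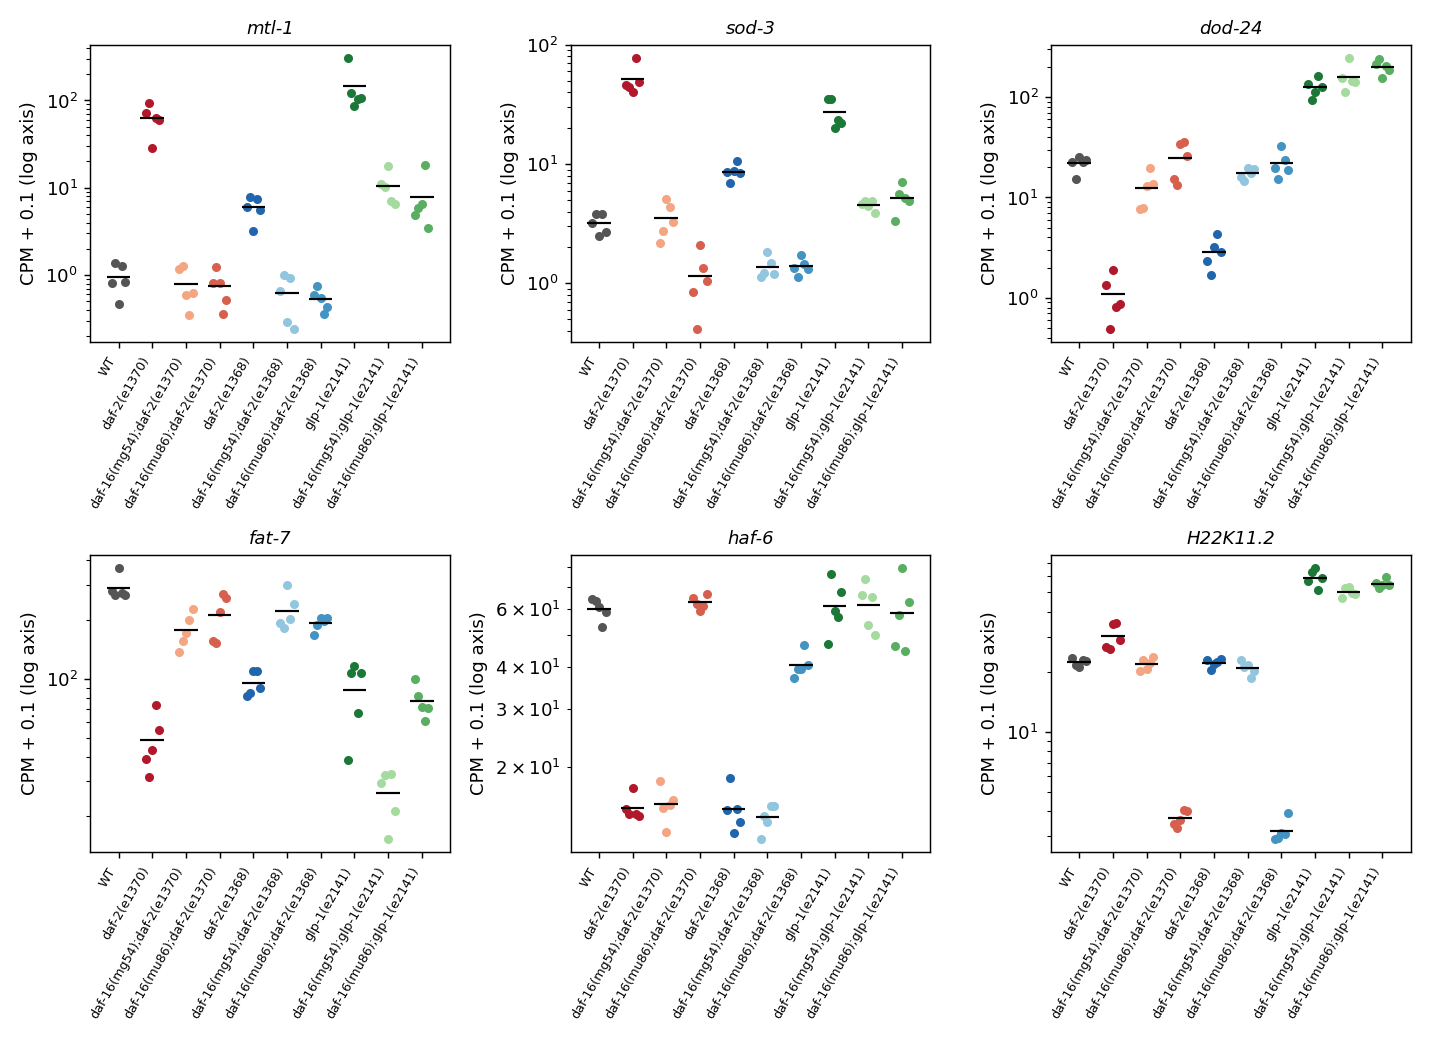
CPM plus 0.1, on a log axis, of mtl-1, sod-3, dod-24, fat-7, haf-6 and H22K11.2 in every library by strain, with a line at the mean of 5. mtl-1 averages 63, 5.94 and 145 CPM in daf-2(e1370), daf-2(e1368) and glp-1 and lies lower in every double, while haf-6 stands at 62.7 CPM in the mu86 double of daf-2(e1370) and 15.4 in the mg54 double.

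Backgrounds were compared through genes called with both daf-16 alleles, with no libraries in common. daf-2(e1370) and daf-2(e1368) shared 153 higher and 85 lower (15 and 7.4 for independent lists), daf-2(e1370) and glp-1 shared 131 and 25 (15.9 and 3.8), and daf-2(e1368) and glp-1 shared 60 and 9 (2.2 and 0.4). Of the genes higher in daf-2(e1370), 990 of 1097 had the same sign in daf-2(e1368) (90.2%) and 883 of 1021 in glp-1 (86.5%). Of the lower ones, 821 of 933 (88%) and 742 of 900 (82.4%) did. The desaturase gene fat-7 differed in direction. The glp-1 single mutant held 86.9 ± 33.1 CPM against 26.1 ± 7.62 with mg54 and 76.9 ± 15 with mu86, or 0.96 ± 0.23 above the mean of its doubles. That call ended without glp-1 replicate 1, 2 or 4 (adjusted p = 0.0578 to 0.0856) and with the replicate block (0.0938).

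**Figure D4:**
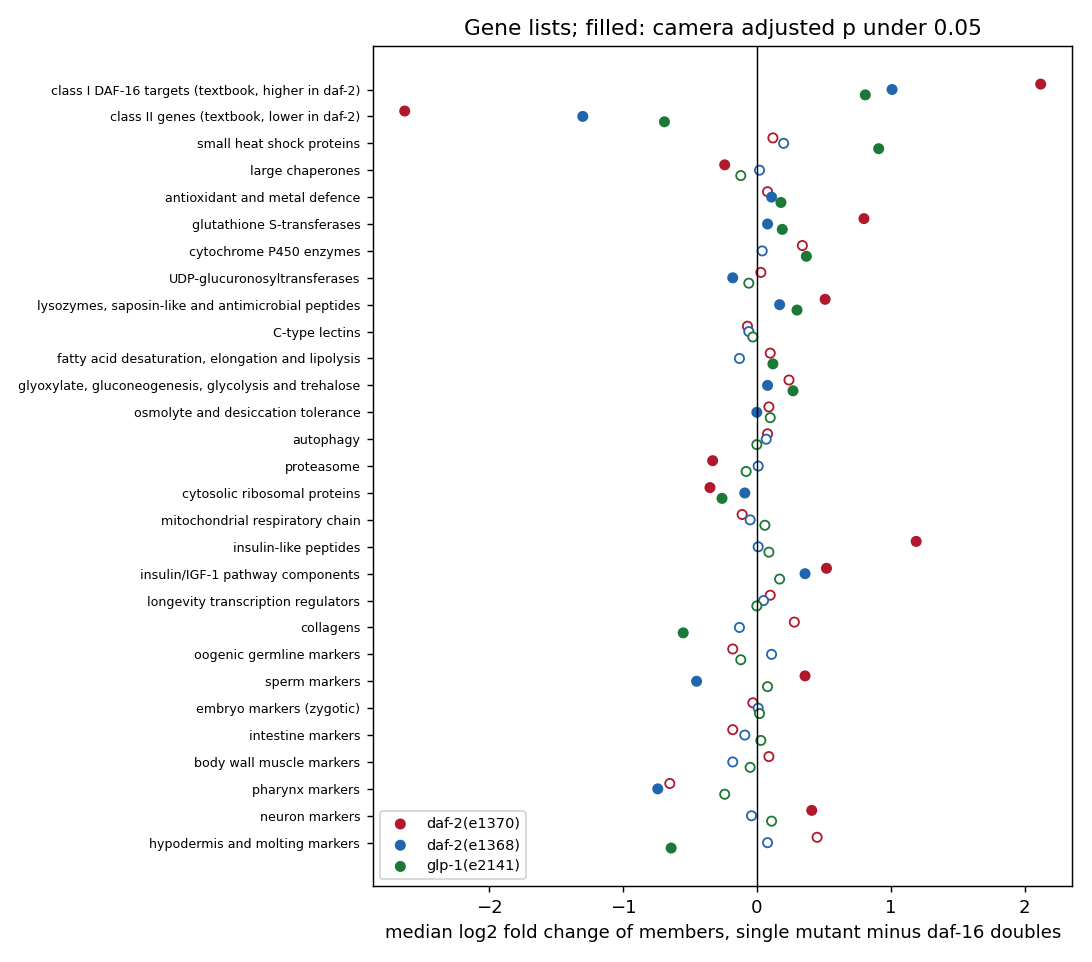
Median log2 difference of list members, single mutant minus the mean of its doubles, in daf-2(e1370), daf-2(e1368) and glp-1, with filled points where the camera adjusted p is under 0.05. Class I genes lie at 2.12, 1.01 and 0.81, and ribosomal protein genes at −0.35, −0.09 and −0.26.

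Higher than in wild type in both daf-2 single mutants were mtl-1 (6.23 ± 0.47 in e1370 and 2.81 ± 0.42 in e1368), sdz-24 (4.73 ± 0.36 and 2.5 ± 0.33), lipl-1 (6.69 ± 0.34 and 2.25 ± 0.31) and lea-1 (2.87 ± 0.1 and 2.49 ± 0.1). Also higher were nspa-4 (2.82 ± 0.53 and 2.37 ± 0.52), spp-2 (2.85 ± 0.19 and 1.71 ± 0.18), ftn-1 (3.69 ± 0.4 and 1.62 ± 0.37) and the RNase H gene rnh-1.3 (2.13 ± 0.15 and 1.55 ± 0.15). Lower were dod-24 (−4.68 ± 0.37 and −2.97 ± 0.31) and fat-7 (−2.57 ± 0.2 and −1.62 ± 0.19). The half-molecule ABC transporter gene haf-6 was lower too (−2.01 ± 0.1 and −2.01 ± 0.1), but the doubles did not share one level. In CPM, WT stood at 59.9, the mu86 doubles at 62.7 with e1370 and 40.6 with e1368 (37.1 to 46.6, against 52.7 to 64.2 in WT), and the mg54 doubles at 15.4 and 14. Also lower were cyp-13A2 (−3.65 ± 0.3 and −1.2 ± 0.25), cutl-18 (−2.17 ± 0.19 and −1.12 ± 0.18), clec-10 (−2.28 ± 0.16 and −0.98 ± 0.15), the collagen gene col-135 (−2.82 ± 0.24 and −0.88 ± 0.22) and ugt-63 (−1.05 ± 0.25 and −0.96 ± 0.25). In e1368 the ftn-1 call ended without WT replicate 0 (adjusted p = 0.0573) and the ugt-63 call without e1368 replicate 1, 2, 3 or 4 or WT replicate 0, 1 or 2 (0.0605 to 0.126). The col-135 call ended without e1368 replicate 0, 1 or 2 or WT replicate 3 or 4 (0.051 to 0.0807).

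For e1370, 2147 entries passed (1158 higher and 989 lower), and for e1368, 243 (146 and 97). With all 50 libraries in 1 fit the majority for e1370 turned, to 989 higher and 1096 lower, and the replicate block gave 3345 (1716 and 1629) and 666 (384 and 282). When loci at 0 in a strain were kept, e1368 gave 371, and the majority turned, to 169 higher and 202 lower. The alleles shared 139 higher and 87 lower (14.4 and 8.1 for independent lists, 0 simulated, 59 and 37 with WT split, where independent lists give 4.8 and 2.6). Of the entries changed against WT in e1370, 844 higher and 678 lower ones were also called with both daf-16 alleles in the same direction (107.9 and 78.4 for independent lists). For e1368 these were 103 and 50 (2 and 0.8). The e1370 libraries serve in both comparisons, so part of this overlap can come from them: set against the daf-16 effect, 1002 and 867 entries were shared, 0 when simulated, and 595 and 332 with the e1370 libraries split (116.4 and 78.8 for independent lists).

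Among groups against wild type, class I genes rose in 17 of 17 in e1370 (17 adjusted over the list alone; adjusted p = 1.6e-30, and adjusted p = 1.54e-05 with an estimated correlation). In e1368 they rose in 12 of 17 (14 adjusted over the list alone; adjusted p = 4.24e-26, and adjusted p = 4.19e-05 with an estimated correlation). Class II genes fell in 3 of 5 (3 adjusted over the list alone; adjusted p = 6.34e-05, and adjusted p = 0.00222 with an estimated correlation) in e1370 and in 2 of 5 (2 adjusted over the list alone; adjusted p = 1.54e-05, and adjusted p = 0.00108 with an estimated correlation). Osmolyte and desiccation genes in e1368 (2 of 7 rose and 0 fell, 2 and 1 adjusted over the list alone; adjusted p = 0.002, and adjusted p = 0.0179 with an estimated correlation) rose through lea-1 and the small heat shock protein gene hsp-12.6 (1.27 ± 0.26). Lysozymes and related peptides rose in 16 of 27 in e1370 (18 and 1 adjusted over the list alone; adjusted p = 4.23e-11, and adjusted p = 0.183 with an estimated correlation). In e1368 they rose in 7 and fell in 1 (11 and 1 adjusted over the list alone; adjusted p = 3.55e-08, and adjusted p = 0.271 with an estimated correlation). Ribosomal protein genes fell in 30 of 53 in e1370 (39 adjusted over the list alone; adjusted p = 1.25e-11, and adjusted p = 0.497 with an estimated correlation). Proteasome genes fell in 10 of 19 (14 adjusted over the list alone; adjusted p = 3.24e-05, and adjusted p = 0.53 with an estimated correlation). Also past the threshold in e1370 were antioxidant and metal defence (6 rose and 1 fell of 17, 7 and 1 adjusted over the list alone; adjusted p = 0.0103, and adjusted p = 0.497 with an estimated correlation) and cytochrome P450 enzymes (14 and 2 of 37, 14 and 2 adjusted over the list alone; adjusted p = 0.00874, and adjusted p = 0.522 with an estimated correlation). The latter call ended without e1370 replicate 0 (0.0554). The respiratory chain was lower (0 and 2 of 17, 0 adjusted over the list alone; adjusted p = 0.0439, and adjusted p = 0.698 with an estimated correlation), a call that ended without e1370 replicate 0 or 1 or WT replicate 0, 1 or 4 (0.053 to 0.161). In e1368 small heat shock proteins passed (2 and 0 of 8, 2 adjusted over the list alone; adjusted p = 0.00823, and adjusted p = 0.175 with an estimated correlation). So did UDP-glucuronosyltransferases (2 and 3 of 39, 2 and 4 adjusted over the list alone; median −0.12, adjusted p = 0.0168, and adjusted p = 0.643 with an estimated correlation), a call that ended without e1368 replicate 1 or WT replicate 3 (0.165 and 0.0681).

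Some tissue marker lists also passed as lower against wild type. In e1370 pharynx markers fell in 2 of 9 (2 adjusted over the list alone; median −0.93, adjusted p = 0.0175, adjusted p = 0.527 with an estimated correlation, and 0.0668 without e1370 replicate 1). In e1368 the lower lists were pharynx (median −0.67, adjusted p = 0.00502, and adjusted p = 0.473 with an estimated correlation), sperm (−0.48, adjusted p = 0.00123, and adjusted p = 0.793 with an estimated correlation) and body wall muscle markers (−0.25, adjusted p = 0.0257, and adjusted p = 0.649 with an estimated correlation). Ribosomal protein genes were lower as a list there too (−0.17, adjusted p = 6.36e-08, and adjusted p = 0.574 with an estimated correlation). In these 4 lists edgeR called 0 members in e1368, over all genes or over the list alone, with 1 of 9, 0 of 51, 1 of 18 and 3 of 53 at an unadjusted p under 0.05, and DESeq2 called 0. The muscle call ended without e1368 replicate 0 or 4 or WT replicate 4 (0.0515 to 0.0797).

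The doubles were set against wild type to ask what remained of the daf-2 change without daf-16. daf-16 itself was lower in the mean of the doubles, by −0.63 ± 0.08 with e1370 and −0.61 ± 0.08 with e1368. Fewer entries passed than for the single mutants: 153 with e1370 (89 higher and 64 lower) and 50 with e1368 (21 and 29). Of these, 39 and 17 were also called in daf-2(e1370) against WT in the same direction (8.8 and 5.4 for independent lists, 0 simulated, 21 and 12 with WT split, where independent lists give 5 and 6.8). For daf-2(e1368) they were 3 and 3 (0.3 and 0.2, 0 simulated, 0 and 1 with WT split, where independent lists give 0.1 and 0.1). Across all 11774 genes the changes of single mutant and doubles were not closely correlated. Pearson's r was 0.021 with e1370 and 0.23 with e1368, and −0.217 and −0.111 with WT split. Simulated unchanged groups that share WT gave 0.563 and 0.579, but lack the real changes that add to the spread of each comparison. The covariances were 0.006 and 0.026, against 0.057 and 0.057 simulated and −0.109 and −0.026 with WT split. The mean of the e1370 doubles includes replicates 0 and 1 of both. These stood apart on the first principal component (−132.4 to −66, against −17.1 to 39.5 in WT), and r was not computed without them. The counts were 90 without WT replicate 4 for e1370 and 32 without WT replicate 3 for e1368, and DESeq2 called 233 (136 higher and 97 lower) and 84 (44 and 40). The replicate block turned the majority for e1370, to 223 higher and 423 lower of 646, and gave 86 (40 and 46) for e1368. Of settings chosen after seeing the data, loci at 0 kept gave 94 higher and 112 lower for e1370. Leaving out replicates 0 and 1 of both daf-2(e1370) doubles gave 146 higher and 40 lower. With all 50 libraries in 1 fit 28 passed for e1368 (8 and 20).

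The mg54 and mu86 doubles were compared to ask whether the 2 daf-16 alleles give the same transcriptome. The gene haf-6 (chromosome I, 1162949 to 1175858) was at 15.4 ± 1.96 CPM in the mg54 double of daf-2(e1370) and 62.7 ± 2.79 in the mu86 double (mg54 minus mu86 −2.02 ± 0.1, adjusted p = 2.78e-16). With e1368 it was at 14 ± 1.28 and 40.6 ± 3.59 (−1.53 ± 0.1, adjusted p = 5.88e-13). WT held 59.9 ± 4.6, daf-2(e1370) 15 ± 1.24, daf-2(e1368) 14.9 ± 2.25, and the glp-1 strains 58.1 ± 14.1 to 61.6 ± 9.69. H22K11.2 (chromosome X, 6784375 to 6787225) went the other way, at 21.8 ± 1.51 and 3.58 ± 0.328 CPM with e1370 (2.6 ± 0.1, adjusted p = 5.9e-19) and 20.7 ± 1.63 and 3.09 ± 0.412 with e1368 (2.75 ± 0.1, adjusted p = 1.68e-19). With e1370 the lysosomal hexosaminidase gene hex-1 (1.37 ± 0.12), the cystatin gene cpi-1 (0.98 ± 0.17) and CELE_Y11D7A.7 (0.54 ± 0.12, adjusted p = 0.0488) were higher with mg54. Higher with mu86 were clec-190 (−2.23 ± 0.44), col-135 (−2.07 ± 0.23), F11D5.1 (−0.96 ± 0.14) and CELE_C50B6.7 (−0.81 ± 0.12). With e1368 rnh-1.3 (1.29 ± 0.15), the dystrobrevin gene dyb-1 (1.29 ± 0.16) and C16A11.5 (1.09 ± 0.13) were higher with mg54. There daf-16 (−0.92 ± 0.09) and T05A12.4 (−0.92 ± 0.16) were higher with mu86. The call of CELE_Y11D7A.7 ended (0.0868 to 0.341) without any 1 library other than mg54 replicate 2 and mu86 replicate 1, and that of clec-190 (0.0511 to 0.0644) without mg54 replicate 3 or 4.

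By edgeR 24 entries differed with e1370 (9 higher and 15 lower with mg54; 378 at unadjusted p under 0.05), 11 with e1368 (5 and 6; 320 unadjusted) and 2 with glp-1 (0 and 2; 439 unadjusted). DESeq2 called 48 with e1370 and 23 with glp-1. When loci at 0 in a strain were kept, a setting chosen after seeing the data, 76 differed with e1370 (55 higher and 21 lower), which turned the majority, and 99 with e1368 (9 and 90). With all 50 libraries in 1 fit 28 differed with glp-1 (16 and 12), which turned it too. With the replicate block the e1370 count was 56, or 1976 when only this pair of strains was fitted with the block and 7 when it was fitted without. The glp-1 calls were daf-16 (−1.43 ± 0.18, adjusted p = 0.00594, and 0.071 with the block) and the entry H36N01.2,H36N01.3,R13H8.4, and 4 entries passed without mg54 replicate 2.

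Whether the size of the daf-16 effect differed between backgrounds was tested directly. The fatty acid and retinol binding protein gene far-3 (chromosome V, 12995406 to 12997535) held 220 ± 150 CPM in daf-2(e1370), and its daf-16 effect was larger there than in daf-2(e1368) by 3.99 ± 0.38 (adjusted p = 1.55e-08). The drop with daf-16 present was deeper in e1370 for oac-20 (−2.87 ± 0.19), cyp-13A2 (−2.22 ± 0.33), msra-1 (−1.7 ± 0.27), sri-40 (−1.59 ± 0.27), dod-24 (−1.56 ± 0.41) and clec-47 (−1.37 ± 0.29). Against glp-1 the effect was larger in e1370 for lipl-1 (5.83 ± 0.43) and sdz-24 (5.63 ± 0.39). It was more negative for dod-24 (−3.9 ± 0.36), sdz-6 (−3.73 ± 0.91), clec-190 (−3.47 ± 0.59), oac-20 (−3.43 ± 0.29), fat-7 (−2.96 ± 0.26) and ugt-53 (−2.63 ± 0.5). The value of sdz-6 was −4.38 without replicate 3 of daf-2(e1370), and that of clec-190 −4.3 without its replicate 0. For fat-7 the glp-1 part rests mainly on mg54, since the mu86 double of glp-1 lay within the range of its single mutant. The dod-24 transcript itself stood at 21.7 ± 3.89 CPM in WT, 0.987 ± 0.552 in daf-2(e1370), 2.79 ± 1 in daf-2(e1368) and 126 ± 25.8 in glp-1.

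Between e1370 and e1368, 555 entries differed (379 with a larger value in e1370 and 176 with a smaller one), or 348 without daf-2(e1368) replicate 1 and 3668 (2187 and 1481) with the replicate block. Between e1370 and glp-1, 893 differed (541 and 352). With RLE factors the e1370 and glp-1 split was 468 and 540, and with DESeq2 543 and 631. The dod-24 call between daf-2 alleles ended without replicate 3 of e1368 or of e1370 (adjusted p = 0.0531 to 0.057). Genes sup-6, his-48, his-62, his-59 and his-63 (7.55 ± 1.71, 4.68 ± 1.12, 4.58 ± 1.1, 4.52 ± 1.05 and 4.29 ± 1.11 between daf-2 alleles) passed through daf-2(e1370) replicate 2 alone. So did his-48, his-62, his-59 and his-61 (5.61 ± 1.32, 5.39 ± 1.06, 5.29 ± 1.18 and 4.42 ± 0.92 against glp-1). Without it their adjusted p were 0.335, 0.443, 0.479, 0.971 and 0.251, and 0.725, 0.724, 0.528 and 0.678.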

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

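Chosen only after the result was seen were the tests of RNA without a poly(A) tail, of depth, of the daf-2(e1370) genotype, of DAF-16 activity left by mg54 and of linkage to chromosome I, while the test of a later stage at harvest and the differences between backgrounds were planned. The genes haf-6, H22K11.2, his-59 and sup-6 were added to the search for outlying libraries after their values were seen. That search covered 100 groups of 5 libraries with a critical value of 0.71 for Dixon's ratio, and chance gives about 1 such group in 20.

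Several transcripts that set daf-2(e1370) apart came from 1 library. In replicate 2, 22 entries, 10 of them histone genes, lay more than 10 times above the other daf-2(e1370) libraries. They also include the protein-coding genes anc-1 (851 CPM against a mean of 77.8 in those libraries), dig-1 (584 against 51.8) and ZC247.1 (386 against 17.2). The 29 snoRNA and snRNA genes outside this set had a median log2 ratio of 3.91 there, in a set narrowed after a first value of 4.07 over 34 genes had been seen, which is consistent with more RNA without a poly(A) tail in that library. In 15 of them with enough fragments elsewhere the ratio was 4.48 above that of protein-coding genes of similar level (quartiles 3.69 to 5.79 against −0.44 to 0.48), which argues against low depth alone, and the other daf-2(e1370) libraries stood only 0.11 above the doubles where replicate 2 stood 4.14 above, which argues against the genotype. Both tests bear on these RNA classes, since the 22 entries were chosen by their excess in that library, and how such RNA entered it was not tested. Also raised in that library were unc-89 (1020 CPM against a mean of 178 without it) and ttn-1 (268 against 44.6). Whether the same cause covers them and anc-1, dig-1 and ZC247.1 was not tested.

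The mg54 and mu86 doubles of daf-2 differed for haf-6, H22K11.2 and F57A10.2 in both daf-2 backgrounds. DAF-16 activity left by mg54 would place its doubles between the single mutant and the mu86 doubles, and for F57A10.2 with e1368 all 5 mg54 libraries (0 to 3 fragments) lay below every library of the single mutant (33 to 87) and of the mu86 double (28 to 62), which argues against it there. For haf-6 and H22K11.2 it stays open, since their median signed difference of −0.11 in the glp-1 doubles comes from a background where daf-16 did not change them past the threshold (edgeR adjusted p = 0.944 and 0.188). Variants linked to daf-16 on chromosome I could not be told apart from other variants or other differences in strain history: with the replicate block for the e1370 doubles, whose numbers pair them, 5 of 60 genes lie on chromosome I against 1734 of 11774 tested (odds ratio 0.53, 95% interval 0.16 to 1.3, one-sided Fisher exact p = 0.953), and without it 4 of 28 (0.96, 0.24 to 2.81, p = 0.608), but with the block on this pair alone 333 of 1979 (1.21, 1.06 to 1.38, p = 0.00241).

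Replicates 0 and 1 of both daf-2(e1370) doubles held few sperm transcripts, with a median log2 difference of −2.85 for sperm markers against their other replicates. Pharynx (−1.74), body wall muscle (−1.19), collagen (−0.96) and neuron (−0.92) genes moved the same way, while oogenic markers were at 0.45 (quartiles 0.35 to 0.54). Lower depth was excluded by the mean log2 totals (−0.03). By the limit set before, the embryo markers (0.08, quartiles −0.28 to 0.21) argued against a later stage at harvest. They move both ways, so that limit was later judged too weak, and fewer sperm and more oogenic transcripts go with a later stage. The design gives no group that separates these libraries, so no other biological explanation was tested, and the cause stays open.

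A single library stood far from the other 4 of its strain in 12 cases, in CPM. In daf-2(e1370) replicate 2 these were daf-16 at 270, daf-2 at 442, glp-1 at 466, haf-6 at 17.2, his-59 at 357 and sup-6 at 151. The others were sod-3 at 77.3 in daf-2(e1370) replicate 3, sup-6 at 0.392 in replicate 2 of the mg54 double of daf-2(e1370), daf-2 at 103 and H22K11.2 at 3.81 in replicates 2 and 4 of the mu86 double of daf-2(e1368), mtl-1 at 305 in glp-1 replicate 0, and mtl-1 at 18.2 in replicate 3 of the mu86 double of glp-1.

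The daf-16 effect differed between backgrounds by a test of the difference. Between daf-2(e1370) and daf-2(e1368) 555 entries passed, among them far-3 (3.99), oac-20 (−2.87), cyp-13A2 (−2.22), msra-1 (−1.7), sri-40 (−1.59), dod-24 (−1.56) and clec-47 (−1.37). The differences of sup-6 (7.55), his-48 (4.68), his-62 (4.58), his-59 (4.52) and his-63 (4.29) rested on daf-2(e1370) replicate 2. The dod-24 difference did not pass without replicate 3 of either single mutant (adjusted p = 0.0531 to 0.057). The count was 348 without daf-2(e1368) replicate 1. Between daf-2(e1370) and glp-1 893 entries passed, among them lipl-1 (5.83), sdz-24 (5.63), dod-24 (−3.9), sdz-6 (−3.73), clec-190 (−3.47), oac-20 (−3.43), fat-7 (−2.96) and ugt-53 (−2.63). There his-48 (5.61), his-62 (5.39), his-59 (5.29) and his-61 (4.42) rested on the same library.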

How the results depend on the processing

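Chosen after seeing the data were entries as deposited without summing, loci at 0 kept, minima of 100 and 10000 for a locus not estimated, the block within a pair of strains, and fits without replicates 0 and 1 of both daf-2(e1370) doubles. Over all settings 432 counts stayed within 1.5 times the reported one and 63 did not. Of values of single genes 20022 stayed, 666 lost and 184 gained their call, 34 moved and 7 turned. Of list results 2312 stayed, 105 lost and 106 gained their call, 83 moved and 4 turned. RLE factors turned no called list. Unless stated below, the cause of a change was not tested.

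With the replicate number as a block the counts were 5347 and 4107 for daf-2(e1370) against its mg54 and mu86 doubles, 696 and 1035 for daf-2(e1368), and 147 and 147 for glp-1. The block gave 3345 and 666 for e1370 and e1368 against WT, 646 and 86 for their doubles against WT, 56 and 1 for mg54 against mu86 in daf-2(e1370) and glp-1, and 3668 for the difference between the daf-2 alleles. A block on the compared pair alone gave 1544 for daf-2(e1368) against its mg54 double and 1976 for mg54 against mu86 in daf-2(e1370). Among list calls the block ended osmolyte tolerance in daf-2(e1368) (0.103), the respiratory chain in daf-2(e1370) against WT (0.0509) and collagens in glp-1 (0.05). It gained oogenic markers in daf-2(e1370) (0.0306), daf-2(e1368) (0.0182) and daf-2(e1368) against WT (0.0178), and collagens in daf-2(e1368) (0.0229). The block changed no other list call. Fitting the compared strains alone gave 1014 and 1313 for daf-2(e1370) against its mg54 and mu86 doubles, 192 for glp-1 against its mu86 double, and 7 for mg54 against mu86 in daf-2(e1370), where fewer libraries estimate the spread.

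A log2 change of at least 1, a stricter test by construction, left 945, 941, 151, 189, 119 and 109 for the 6 single against double comparisons in the same order, 786 and 101 against WT, 62 and 22 for the doubles against WT, 267 and 529 for the differences between backgrounds, and 36 for the genes changed in all 6. DESeq2, which made more wrong calls on simulated data, called 623 and 603 in glp-1, 233 and 84 for the doubles against WT, 48 and 23 for mg54 against mu86 in daf-2(e1370) and glp-1, and 1.0e2 to 2 digits for the genes changed in all 6. With all 50 libraries in 1 fit there were 724 and 527 calls in glp-1, most of them lower (304 higher and 420 lower with mg54, 248 and 279 with mu86, against 245 and 71, and 205 and 117, reported), 28 for the e1368 doubles against WT and 28 for mg54 against mu86 in glp-1 (16 higher and 12 lower). With loci at 0 kept there were 371 for daf-2(e1368) against WT and 76 (55 higher and 21 lower, against 9 and 15) and 99 (9 and 90, against 5 and 6) for mg54 against mu86 in daf-2(e1370) and daf-2(e1368). The stricter filter left 43 genes changed in all 6. An estimated correlation left 10 of the 58 list calls.

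Leaving out 1 library gave 1962 to 3126 and 2188 to 2536 for daf-2(e1370) against its doubles, 227 to 285 and 352 to 472 for daf-2(e1368), and 162 to 397 and 190 to 586 for glp-1. Against WT it gave 1763 to 2115 and 165 to 208, and 90 to 183 and 32 to 53 for the doubles. For mg54 against mu86 it gave 20 to 31, 11 to 12 and 2 to 4, for the differences between backgrounds 348 to 705 and 716 to 1064, for the genes changed in all 6 52 to 75, and for list calls 57 to 64. Counts moved by over 1.5 times without single libraries: in glp-1 against mg54, 181, 191 and 199 without glp-1 replicates 0, 2 and 4, and 162, 208 and 174 without mg54 replicates 0, 1 and 3. Against mu86 they were 200 without glp-1 replicate 0 and 196, 204, 586 and 190 without mu86 replicates 1, 2, 3 and 4. The others were 90 without WT replicate 4 and 32 without WT replicate 3 for the e1370 and e1368 doubles, 4 without mg54 replicate 2 in glp-1, and 348 without daf-2(e1368) replicate 1.

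Without daf-2(e1370) replicate 2 the signs turned, and without replicate 0 they were highest. The gene mrpr-1 against mg54 went from −0.24 to 5.16, and his-62 from −0.34 to 4.97 against mg54, −0.4 to 4.9 against mu86 and −0.37 to 4.93 against both. In the difference between the daf-2 alleles his-62 went from −0.3 to 4.99, his-48 from −0.34 to 5.09 and his-63 from −0.62 to 4.71. By fry, embryo markers (0.00653) and intestine markers (0.0175) in daf-2(e1370) were called higher. Without replicates 0 and 1 of both daf-2(e1370) doubles, body wall muscle markers (0.0491) and sperm markers (0.0371) turned lower, and the counts were 2078 and 2697 for daf-2(e1370) against its doubles. With RLE factors the difference between daf-2(e1370) and glp-1 split into 468 higher and 540 lower, against 541 and 352, with a median shift of −0.089. Depth limits daf-2(e1370) replicate 2 most, with 2.37 in units of 1e6 fragments.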

Other observations

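The tests of other splits in this part were written before the results were seen, and a second draw for 1 of them was added after.

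Some gene groups not described above moved in glp-1 and in daf-2 against WT. Collagen genes, which form the cuticle, had a median of −0.55 in glp-1 against its doubles (3 of 91 rose and 0 fell, 3 adjusted over the list alone, adjusted p = 0.0455, and adjusted p = 0.818 with an estimated correlation), while those called rose. The call was lost (0.0504 to 0.449) without glp-1 replicates 0, 1 or 4, mg54 double replicates 0, 3 or 4, or mu86 double replicates 0, 1, 2 or 4. In daf-2(e1370) against WT, insulin-like peptide genes rose in 8 and fell in 1 of 18 (9 and 1 adjusted over the list alone, adjusted p = 0.0134, and adjusted p = 0.503 with an estimated correlation). Glutathione S-transferases, which bind toxins to glutathione, rose in 12 and fell in 2 of 34 there (15 and 3 adjusted over the list alone, adjusted p = 0.00163, and adjusted p = 0.49 with an estimated correlation). Antioxidant and metal defence genes rose in 5 and fell in 0 of 17 in daf-2(e1368) against WT (6 adjusted over the list alone, adjusted p = 5.39e-06, and adjusted p = 0.183 with an estimated correlation).

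Other splits of the same libraries into groups of equal sizes were counted, 100 for each result with the real one included, on the compared strains alone. For daf-2(e1370) the real split gave 1014 calls against mg54 (highest other 39) and 1313 against mu86 (highest other 731), for daf-2(e1368) 320 (10) and 545 (1), for daf-2(e1370) against WT 1650 (1), for glp-1 against mu86 192 (158), for mg54 against mu86 in daf-2(e1368) 12 (1), for the difference between daf-2(e1370) and glp-1 566 (0), and for the genes changed in all 6 66 (0). In each of these 1 of 100 splits, the real one, was as large, which meets the limit set before for excluding chance. For the list calls, with libraries reassigned within each family, 1 of 100 was as large too, but the highest other gave 57 against 58. That margin is too small to exclude chance for the number of list calls, and 10 of the 58 held with an estimated correlation.

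In 5 results 2 of 100 splits were as large. That meets the limit, but the other split called more, so chance is not excluded. These were glp-1 against mg54 (266, highest other 588), daf-2(e1368) against WT (325 and 1354), the e1370 doubles against WT (98 and 1587), the e1368 doubles against WT (53 and 575) and the difference between the daf-2 alleles (447 and 547). The split with 547 left every single mutant library in its own group and moved doubles only. For mg54 against mu86 in glp-1 3 of 100 were as large (2 and 958), which leaves chance open there too. Splits that call several times the real count point to a structure of the samples beyond strain.

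For mg54 against mu86 in daf-2(e1370) 5 of 100 splits were as large (7, highest other 7352), so chance cannot be excluded by this count, while a second draw gave 3 of 100. The split with 7352 put replicates 0 and 1 of both doubles on the same side, which are the libraries with few sperm transcripts. Replicate numbers pair these samples, and of the 16 splits that part all 5 pairs the real one gave 7 and the highest other 0. The same count for daf-2(e1368) against its mg54 double was 320 and 0.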
